A study of Danio rerio with 20 samples.

How the data were processed

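Whole zebrafish larvae of the AB strain were kept from 6 to 96 hours post fertilization (hpf) with a mixture of persistent organic pollutants (POP), with perfluorooctanesulfonic acid (PFOS) alone, or with the solvent, 0.1% dimethyl sulfoxide. The sample labels give the solvent level for Control only, so they do not show that the exposed larvae had the same level. The labels give the mixture as scaled to blood levels in a Scandinavian population, at 10 times those levels (POP10) and at 70 times (POP70), with PFOS alone at the amounts it has in each mixture (PFOS10 and PFOS70). Per the labels, each of the 5 groups had 4 samples, and each sample held 10 larvae. RNA was purified with poly-T beads and made into libraries with a kit whose protocol, as labelled, fragments the RNA and primes at random. The strand setting of the counting is not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. How reads that match several near-identical copies were counted is not given either, so values of such genes are uncertain to a degree that was not tested.

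The authors deposited 1 table of 48838 transcripts with a log2 value per library. The submitters' processing notes name Trim Galore 0.4.5, STAR 2.5.4b, DESeq2, R 3.5.0 and the genome build GRCz11, with no role or order. The step that turned alignments into log2 values is not given in the sources used here. From the values, each deposited log2 value is the log2 of RPM (reads scaled to a common total), not divided by transcript length, with a transcript of 0 reads written as 0.9 reads. When values were divided by the worth of 1 read, 100% of those from 1 to 1000 reads came out whole within 0.05 reads. This gave 8572287 to 11243573 reads per library as the total that RPM values refer to, so 1 RPM stood for 8.57 to 11.2 reads. Each column summed to 3126704 to 3390337 RPM, more than the common total to which RPM values are scaled, and the reason was not tested. The counting error covered by these depths is that of reads, not of molecules.

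Transcripts were named by the row name of the table, which differed from its feature name in 1662 transcripts (3.4%). For each of 22887 genes the transcript with the highest mean over the 20 libraries was taken, a choice made after the table had been looked at, and 9882 genes had 1 transcript. Genes with at least 0 log2 RPM in at least 4 libraries were tested, which left 19298. The design fixed before the data were examined had assumed log2 normalized counts, with this filter as its stated branch for RPM values, and no further pseudocount was added. Fold changes of low genes are understated by the 0.9 reads that stand for 0.

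Differences between groups were tested with limma 3.58.1 in R 4.3.3, by 1 linear model over the 20 libraries with the group as its only term and 15 residual degrees of freedom. The moderated two-sided test used a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. The 8 comparisons were each exposure with Control, the mixture with PFOS at each level, and the higher with the lower level of each. The 45 gene lists, the comparisons and most alternatives were fixed before the data were examined. In 6 comparisons the lists were tested with camera of limma, at a preset inter-gene correlation of 0.01 and then with an estimated correlation, and adjusted over the 45 lists. Members were also counted with p-values adjusted over the list alone. These counts were not adjusted over the 45 lists or over the comparisons. Members of a list can be correlated, with an estimate of 0.733 for hepatocyte secreted proteins, so the counts are not numbers of independent calls. A test of the difference between the dose effects of the mixture and of PFOS was added after the data were seen.

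Named genes followed a rule fixed before the data were examined. It took the 6 largest changes in each direction among genes past the threshold with non-overlapping groups, a mean of at least 5 log2 RPM and a gene symbol that is no clone name. In the dose comparisons it took 3 in each direction. From each list it took up to 3 members past the threshold, and these are named only for lists described here and not where a group mean lay below 0 log2 RPM. Where fewer than 12 genes passed, it also took the 5 of smallest unadjusted p in each direction, as values. Genes of a fixed set of detoxification, lipid, stress and calcium genes were also given. Not all of this set is used here.

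The alternatives were no filter, a stricter filter of 5.5 log2 RPM, damping by 16 RPM, quantile normalization, a shift to equal medians, no variance trend, array weights, the replicate number as a block, only the 2 groups compared, each library left out, and limma voom on recovered reads. Chosen after seeing the data were the lowest-numbered transcript of each gene, all transcripts, and a fit without the PFOS10 libraries. Each comparison was repeated over the 35 splits of its 8 libraries into 4 and 4, and the difference of dose effects over 100 groupings of the exposed libraries. Libraries were also thinned to the 8572287 reads of the shallowest. Correlations of fold changes that share the controls were set beside 100 simulations with no effect and beside 6 splits of the controls.

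The gene test was tested on simulated data with known changes and with residuals drawn independently between genes. For PFOS10 against Control it recovered 59.7% of 1.5-fold, 80.6% of 2-fold and 90.9% of 4-fold changes among 19298 genes, with 8 false calls. For POP70 against Control the shares were 58.2%, 80.6% and 90.9%, with 9 false calls. The list test, run for PFOS10 against Control with the intestine list shifted by 0.5 log2, called that list (adjusted p = 4.66e-06) and 0 of the 44 others. Residuals were drawn independently here too, while in the real data cytosolic ribosomal protein genes had an estimated correlation of 0.78. The run therefore cannot show how often lists of correlated genes are called with no effect. No checks of GC content or transcript length were run, as no genome was used here.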

Results

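Gene expression was measured by RNA sequencing of whole larvae at 96 hpf in 20 libraries, 4 from each of the Control, POP10, POP70, PFOS10 and PFOS70 groups. Each library came from a separate pool of 10 larvae. The labels do not say that pools came from separate clutches, so p-values measure the spread between these pools. Mean depth was 10734781 ± 393615 reads in Control (SD, n = 4), 9704866 ± 602374 in POP10, 8848344 ± 216019 in POP70, 9973967 ± 160980 in PFOS10 and 10181646 ± 1090236 in PFOS70, and the range over libraries was 8572287 to 11243573. Libraries of 1 group correlated at 0.972 to 0.988 across the 19298 genes tested. Transcripts with over 20 reads and equal reads in a pair of libraries made up at most 1.29% of all transcripts, so no library appeared to have been deposited again under another name.

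The first principal component held 39.6% of the variance and set the PFOS10 libraries apart. These lay at 49.3 to 61.6 on it, against -14.8 to 22.0 in Control, -45.1 to -9.40 in PFOS70, -26.7 to -3.59 in POP10 and -35.3 to 9.86 in POP70. More transcripts had 0 reads in PFOS10, 4044 ± 50.8 (SD, n = 4), than in Control, 3594 ± 121, or in PFOS70, 3476 ± 178. The labels give no batch, day or clutch, so a batch that coincided with a group could not be separated from it.

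**Figure D1:**
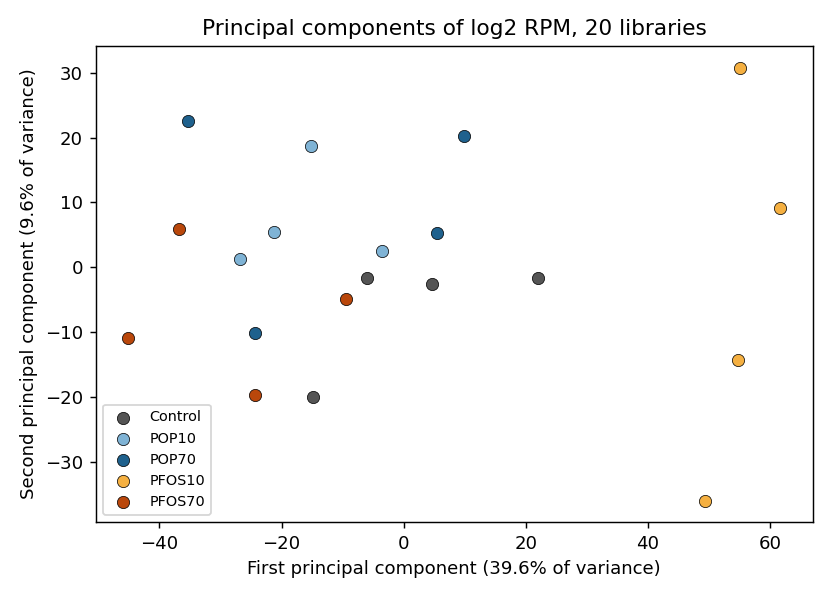
Position of the 20 libraries on the first (39.6% of variance) and second (9.6%) principal components of log2 RPM, in arbitrary units, 1 point per library and 1 colour per group. The 4 PFOS10 libraries lie at 49.3 to 61.6 on the first component, to the right of the other 16 libraries.

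The first question was what the mixture at 70 times blood levels did to expression. In POP70 larvae lonrf1l, a gene of the LON-domain RING finger family, rose to 6.91 ± 0.14 from 6.31 ± 0.11 log2 RPM in Control (SD, n = 4 each). fam46ab, of the nucleotidyltransferase fold family, fell from 5.68 ± 0.21 to 4.66 ± 0.15, and six3b, a homeobox gene of forebrain and eye, fell from 6.35 ± 0.08 to 5.82 ± 0.15. The log2 differences were 0.61 ± 0.07 (SE, limma adjusted p = 0.000776) for lonrf1l at chromosome 8, 13769514 to 13788311 of GRCz11, -1.02 ± 0.13 (adjusted p = 0.00116) for fam46ab at chromosome 23, 40275601 to 40286059, and -0.54 ± 0.08 (adjusted p = 0.00629) for six3b at chromosome 12, 25600685 to 25603341. In each of them the 4 POP70 values lay outside the range of the 4 Control values. These were the 3 of 19298 genes that passed, while 1968 had an unadjusted p under 0.05, where 965 is the mean expected with no effect. How far such a count strays from 965 in correlated genes was not tested. Voom on recovered reads also called 3 genes. Fitted on the POP70 and Control libraries only, 0 genes passed, and adjusted p was 0.136 for lonrf1l, 0.0658 for fam46ab and 0.237 for six3b. The number was 9 without Control replicate 4, and six3b missed the threshold without Control replicate 1 (adjusted p = 0.0505) or replicate 2 (0.0525).

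Among genes that did not pass in POP70, the smallest unadjusted p-values belonged to arrdc3b (log2 difference 1.28 ± 0.24 SE, adjusted p = 0.0665), nfil3 (0.36 ± 0.08, 0.196), arrdc3a (0.56 ± 0.13, 0.196) and kansl1l (1.18 ± 0.28, 0.198) on the higher side. On the lower side were bhlhe22 (-0.47 ± 0.08, 0.0547), six3a (-0.43 ± 0.08, 0.0665) and bhlhe23 (-0.49 ± 0.09, 0.0665). The arrdc3 genes encode arrestin-domain proteins, nfil3 a clock-linked transcription factor, and bhlhe22 and bhlhe23 neuronal transcription factors. Of the fixed set, cyp1a, the classic target of the aryl hydrocarbon receptor, was at 3.26 ± 0.52 log2 RPM in POP70 and 3.15 ± 0.45 in Control, and cyp1b1 at 2.63 ± 0.20 and 2.75 ± 0.23. Values for fkbp5, a chaperone gene induced by glucocorticoids, were 8.6 ± 0.20 and 7.85 ± 0.69 (adjusted p = 0.409). Of the rest of the set, the cytochrome cyp3a65, the fatty acid oxidation genes cpt1ab and cpt1b, the sterol gene hmgcra, the gluconeogenic pck1, the muscle calcium genes ryr1b, atp2a1, cacna1sb and pvalb4, and gad1b, which makes the transmitter GABA, had adjusted p-values of 0.425 to 0.997.

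Of the 45 gene lists, 20 were shifted in POP70 at the preset correlation, 13 higher and 7 lower. The 75 cytosolic ribosomal protein genes had a median log2 difference of 0.15 (camera adjusted p = 2.02e-17), and the 16 cardiac muscle genes one of 0.53 (3.5e-07). Lower were neuron and synapse markers (39 genes, median -0.19, 9.86e-09), photoreceptor genes (48 genes, -0.22, 1.51e-10), calcium channels (41 genes, -0.18, 0.000652) and immediate early genes (25 genes, -0.18, 3.26e-06). No list kept its call: adjusted p = 0.667 with an estimated correlation for each of these 6. Over all genes tested, 0 members of these lists passed. Adjusted over the list alone, 13 photoreceptor genes, 3 neuron markers and 5 immediate early genes fell, 1 cardiac gene rose, and 0 calcium channel and 0 ribosomal protein genes passed.

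At 10 times blood levels, the mixture gave no gene past the threshold. The smallest unadjusted p-values on the higher side were those of hsd3b1, a steroid-synthesis gene (0.80 ± 0.51 log2 RPM against -1.20 ± 0.26 in Control, SD, n = 4, a level of few reads), lonrf1l (log2 difference 0.33 ± 0.07 SE), pik3r3a (0.67 ± 0.15), gng13a (0.86 ± 0.20) and the myosin gene myh7l (1.52 ± 0.36). On the lower side were gpr22b (-0.49 ± 0.12), abrab (-0.53 ± 0.13), six3b (-0.31 ± 0.08), zbtb38 (-0.63 ± 0.16) and zmynd8 (-0.42 ± 0.11), each of the 10 with limma adjusted p = 0.51. For the fixed set, log2 differences ran from -0.31 ± 0.12 for atp2a1, the muscle calcium pump (adjusted p = 0.51), to 0.98 ± 0.26 for fkbp5 (0.51). With limma 0 of 19298 genes passed, 1857 had an unadjusted p under 0.05 and voom called 0. Without Control replicate 4 the number was 3, and it was 4 when only the POP10 and Control libraries were fitted.

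In POP10, 17 lists were shifted, 13 higher and 4 lower. All 75 cytosolic ribosomal protein genes had positive differences (median 0.20, camera adjusted p = 8.79e-31), with 0 past the test over all genes and 16 higher adjusted over the list alone. The cardiac muscle list (16 genes, median 0.49, 1e-06) had 9 members higher adjusted over the list alone. Skin keratinocyte genes (25 genes, median 0.29, 2.22e-05) and hepatocyte secreted proteins (29 genes, 0.43, 0.000476) were also higher, and neuron and synapse markers lower (39 genes, -0.17, 3.91e-08), each with 0 members past either adjustment. Each of these 5 lists had adjusted p = 0.728 with an estimated correlation. Without Control replicate 3 the number of lists was 10.

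The levels of the mixture were then compared with each other. No gene differed between POP70 and POP10 larvae: 0 of 19298 passed with limma, the smallest adjusted p was 1, and voom called 0. An unadjusted p under 0.05 was reached by 580 genes, below the mean of 965 expected with no effect. lonrf1l stood at 6.91 ± 0.14 in POP70 and 6.64 ± 0.06 in POP10, and six3b at 5.82 ± 0.15 and 6.04 ± 0.05 (log2 RPM, SD, n = 4). The groups did not overlap in 374 genes (1.94%), against 2.86% by chance. A median standard error of 0.13 log2 per gene bounds what these libraries could show.

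PFOS alone, at the amount in the stronger mixture, likewise gave no gene past the threshold. The lowest p-value was that of pax6a, a transcription factor gene of eye and brain, at 7.36 ± 0.13 log2 RPM in PFOS70 and 7.82 ± 0.14 in Control (SD, n = 4, log2 difference -0.46 ± 0.08 SE, limma adjusted p = 0.0914). Next on the lower side were pax6b (-0.46 ± 0.08), foxg1b (-0.47 ± 0.09), the RNA-binding gene rbpms2b (-0.39 ± 0.07) and vsx1 (-0.53 ± 0.10), each with adjusted p = 0.132. On the higher side, also at 0.132, were otomp, an otolith matrix gene (2.47 ± 0.48), klhl43 (0.63 ± 0.13), the actin gene actc1c (0.42 ± 0.08), the purinergic receptor gene p2rx3b (0.74 ± 0.15) and the muscle filament gene sync (1.02 ± 0.21). In the fixed set, cyp3a65 was at 6.82 ± 0.66 in PFOS70 and 5.68 ± 1.02 in Control (adjusted p = 0.396), and pvalb4, a calcium-buffering parvalbumin of muscle, at 9.67 ± 0.05 and 9.31 ± 0.12 (0.225). With limma 0 of 19298 genes passed, 2259 had an unadjusted p under 0.05 and voom called 0. The number was 16 without Control replicate 4, 5 without PFOS70 replicate 3, 7 after quantile normalization, 4 after a shift to equal medians and 6 with only these groups fitted. It was 15 (9 higher) with the replicate number as a block, 7 with array weights and 3 with the stricter filter.

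In PFOS70, 27 lists were shifted, 18 higher and 9 lower. Hepatocyte secreted proteins stood highest, with 29 of 29 differences positive and a median of 1.13 (camera adjusted p = 9.8e-17), with 0 members past the test over all genes and 28 higher adjusted over the list alone. Lens crystallins (42 genes, median 0.68, 2.54e-12), exocrine pancreas enzymes (20 genes, 0.78, 0.000168) and cardiac muscle genes (16 genes, 0.56, 3.12e-07) had 6, 2 and 6 members higher adjusted over the list alone. Calcium stores, release and pumps (44 genes, median 0.14, 0.00114) lay higher, with 2 members past the threshold adjusted over the list alone. Photoreceptor genes (48 genes, -0.15, 2.28e-10) and calcium channels (41 genes, -0.12, 0.00114) lay lower, with 0 members. For all 7 of these, adjusted p = 0.503 with an estimated correlation. The list of calmodulin, CaM kinases and calcineurin was called lower (0.0456, and adjusted p = 0.723 with an estimated correlation) with a median of -0.05 and a mean of 0.01, which differ in sign.

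Of the 4 exposures, PFOS10 had the most genes past the threshold. pck1, the rate-limiting enzyme gene of gluconeogenesis, fell from 7.74 ± 1.0 to 4.55 ± 0.95 log2 RPM (SD, n = 4 each), 9.14-fold, and rhcga, an ammonia transporter gene of ionocytes, from 5.74 ± 0.55 to 3.51 ± 0.38, 4.7-fold. klf9, a transcription factor induced by glucocorticoids, fell from 5.04 ± 0.63 to 2.53 ± 0.32, and fkbp5 from 7.85 ± 0.69 to 6.31 ± 0.44. opn1lw2, a red cone opsin, rose from 10.71 ± 0.08 to 11.21 ± 0.09. The log2 differences were -3.19 ± 0.46 (SE, limma adjusted p = 0.00106) for pck1 at chromosome 6, 60055168 to 60062097, -2.23 ± 0.29 (0.000695) for rhcga at chromosome 7, 14291323 to 14302716, -2.51 ± 0.27 (6.42e-05) for klf9 at chromosome 5, 26075230 to 26078165, -1.54 ± 0.26 (0.00247) for fkbp5 at chromosome 6, 41096058 to 41116053, and 0.50 ± 0.09 (0.00466) for opn1lw2 at chromosome 11, 25481046 to 25483206. In all 5 the 4 PFOS10 values lay outside the range of the Control values.

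**Figure D2:**
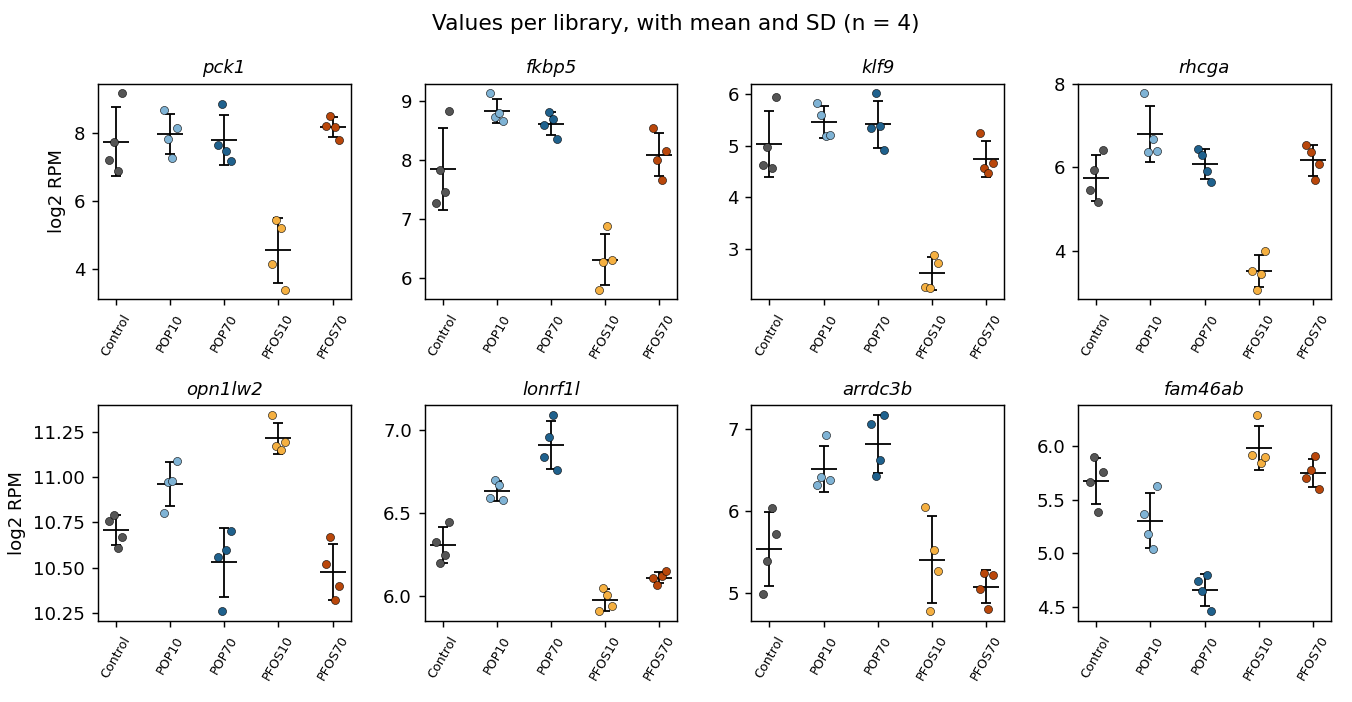
Log2 RPM of 8 genes in each library (points), with the group mean (long line) and SD (whiskers, n = 4), in Control, POP10, POP70, PFOS10 and PFOS70; the vertical axes do not start at 0. Values of pck1 lie at 4.55 ± 0.95 in PFOS10 against 7.74 ± 1.0 in Control, and those of fam46ab at 4.66 ± 0.15 in POP70 against 5.68 ± 0.21 in Control.

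Against Control, 1592 of 19298 genes (8.25%) passed in PFOS10, 247 higher and 1345 lower, and 4901 had an unadjusted p under 0.05. A change of at least 2-fold was seen in 467 of the lower and 2 of the higher genes. The groups did not overlap in 2311 of the 19298 genes (11.98%), against 2.86% by chance, and in 1086 of the 1592. The share that rose depended on the processing: 256 of 798 genes rose after quantile normalization and 1160 of 2248 after a shift to equal medians, where PFOS10 medians lay lower by -0.09 log2. With the stricter filter 187 of 610 rose, with damped values 187 of 769 and with array weights 1101 of 3664. Voom called 1125 genes and a fit of only these groups 934, of which 219 and 70 rose. Single libraries moved the number, to 737 (62 higher) without Control replicate 1, 657 (99 higher) without replicate 2 and 368 (24 higher) without replicate 4, and to 723, 739 and 2518 (47, 67 and 863 higher) without PFOS10 replicates 1, 3 and 4.

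Among genes with a gene symbol that is no clone name, a mean of at least 5 log2 RPM and non-overlapping groups, the largest falls were those of pck1 and rhcga, followed by g6pca.2, the glucose-6-phosphatase gene of the last step of glucose release (-1.91 ± 0.32 SE, limma adjusted p = 0.0024), and2, an actinodin of the fin fold (-1.77 ± 0.27, 0.00113), zanl (-1.71 ± 0.35, 0.00817) and pvalb8, a parvalbumin (-1.69 ± 0.41, 0.0194). Within the same limits the largest rises were those of serpinh1b, a collagen chaperone (0.76 ± 0.18, 0.017), gadd45gb.1 (0.62 ± 0.13, 0.00779), rsrp1 (0.57 ± 0.12, 0.00925), the retinal homeobox gene rx1 (0.56 ± 0.10, 0.0046), the splicing factor gene srsf1b (0.50 ± 0.09, 0.00258) and opn1lw2. Of 48 named genes past the threshold in PFOS10, 33 passed with each of the 8 libraries left out in turn and 41 under both other scalings. Control replicate 4 alone decided serpinh1b (adjusted p = 0.0766 without it), apoa4b.1 (0.0684) and krt91 (0.0575). pvalb8 missed the threshold without it or without PFOS10 replicate 1 (up to 0.0665).

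Lists of liver, lipoprotein, intestine and exocrine pancreas genes fell in PFOS10, in the 4 libraries that stood apart on the first component, while islet hormones were not shifted (14 genes, camera adjusted p = 0.39). Hepatocyte secreted proteins had a median log2 difference of -1.40, and 15 of 29 fell over all genes and 26 adjusted over the list alone, among them rbp4, the retinol carrier (-0.70 ± 0.15 SE, limma adjusted p = 0.00925). Of 21 lipoprotein and yolk genes, 14 fell, and 18 adjusted over the list alone (median -1.22), with apoa4b.1 (-1.42 ± 0.32, 0.0141) and apodb (-0.83 ± 0.17, 0.00885). Intestine genes had a median of -1.38, with 12 of 24 lower over all genes and 22 adjusted over the list alone. Among them were mep1a.2 (-1.80 ± 0.33, 0.00443) and mep1a.1 (-1.81 ± 0.37, 0.008), which encode brush-border proteases. Camera adjusted p-values were 4.99e-13, 1.4e-09 and 6.11e-11, and adjusted p = 0.331 with an estimated correlation for each of these lists. Exocrine pancreas enzymes (median -1.51, 7 of 20 lower and 12 adjusted over the list alone) included ctrl (-2.00 ± 0.50, 0.0214) and ela3l (-2.01 ± 0.53, 0.0256), digestive proteases. Their camera adjusted p was 6.05e-06, and adjusted p = 0.398 with an estimated correlation. ctrl passed without 5 of the 8 libraries, not without Control replicate 2 or 4 or PFOS10 replicate 1 (up to 0.0642), and ela3l missed without those and PFOS10 replicate 4 (up to 0.0886).

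Lists of glucose and amino acid metabolism, glucocorticoid response, fatty acid oxidation and xenobiotic metabolism were also lower in these libraries. Stress axis and steroid synthesis (13 genes, median 0.14, camera adjusted p = 0.533), fatty acid and triglyceride synthesis (23 genes, 0.358) and sterol synthesis (26 genes, 0.946) were not shifted. Of 32 genes of glucose and amino acid metabolism, 17 fell, and 24 adjusted over the list alone (median -0.70, camera adjusted p = 4.33e-12), with pck1, g6pca.2 and gnmt, a methyltransferase of glycine (-0.97 ± 0.17 SE, limma adjusted p = 0.0028). In the glucocorticoid response list 8 of 21 fell and 0 rose, with 11 lower and 1 higher adjusted over the list alone (median -0.37, 9.67e-06). Beside klf9, fkbp5 and pck1 stood tsc22d3, an anti-inflammatory target of the receptor (-0.69 ± 0.11, 0.00213). Fatty acid oxidation and PPAR targets had 17 of 59 lower and 1 higher, and 35 lower and 1 higher adjusted over the list alone (median -0.27, 9.89e-10). These included ucp2, an uncoupling protein (-1.04 ± 0.16, 0.00137), angptl4, an inhibitor of lipoprotein lipase (-0.59 ± 0.09, 0.00195), and pdk2b, a kinase that limits pyruvate oxidation (-1.69 ± 0.30, 0.00376). For these lists adjusted p = 0.331 with an estimated correlation. Xenobiotic metabolism genes under the pregnane X receptor and others had 13 of 47 lower and 27 adjusted over the list alone (median -0.64, 4.74e-10, and adjusted p = 0.339 with an estimated correlation), with the efflux pump gene abcg2a (-1.10 ± 0.26, 0.0162). abcg2a missed without Control replicate 2 or 4 (up to 0.0738).

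In the fixed set, PFOS10 larvae had lower cyp1a (-1.0 ± 0.29 SE, limma adjusted p = 0.0381), cyp3a65 (-1.70 ± 0.51, 0.0448) and cpt1b (-0.62 ± 0.18, 0.0355). Each of these calls was lost without Control replicate 4 (adjusted p = 0.151, 0.162 and 0.127) and after quantile normalization (0.0768, 0.0672 and 0.0638). They were lost also without Control replicate 2, PFOS10 replicate 1 or PFOS10 replicate 3, cyp3a65 and cpt1b without Control replicate 1, and cyp1a and cyp3a65 without PFOS10 replicate 4. After a shift to equal medians cpt1b was lost too (0.0534). cpt1ab (-0.34 ± 0.11, 0.0621), hmgcra (0.16 ± 0.12, 0.447), cyp1b1 (0.10 ± 0.17, 0.762) and gad1b (0.12 ± 0.14, 0.647) did not pass.

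Skin, ionocyte, skeletal and pigment groups were lower in the same PFOS10 libraries. Of 25 skin keratinocyte genes 14 fell, and 18 adjusted over the list alone (median -0.64, camera adjusted p = 1.71e-10), with the keratins krt15 (-0.95 ± 0.18 SE, limma adjusted p = 0.00577) and krt91 (-0.67 ± 0.15, 0.0145) and the annexin anxa1a (-0.77 ± 0.16, 0.00831). Of 21 ionocyte genes 8 fell, and 13 adjusted over the list alone (-0.65, 2.12e-06), with rhcga, its relative rhcgb (-1.40 ± 0.26, 0.00466) and the salt cotransporter slc12a10.2 (-1.16 ± 0.19, 0.00193). Cartilage and bone genes had 3 of 29 lower and 16 adjusted over the list alone (-0.37, 1.75e-05), with col10a1a, a collagen (-1.36 ± 0.28, 0.00769). For these lists adjusted p = 0.331 with an estimated correlation. Pigment cell genes had 8 of 25 lower, and 8 adjusted over the list alone (-0.18, 0.00509), with gch2, of pteridine synthesis (-0.94 ± 0.17, 0.00485), and inflammation genes 5 of 32 and 8 (-0.39, 0.000319), with nfkbiaa (-1.18 ± 0.18, 0.00106) and socs3a (-1.24 ± 0.25, 0.00794), feedback inhibitors of cytokine signalling. For both, adjusted p = 0.339 with an estimated correlation.

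Calcium genes, named in the title of the series, moved in both directions in PFOS10. Of 44 genes of calcium stores, release and pumps 4 fell, and 9 adjusted over the list alone (median -0.15, camera adjusted p = 0.0164, and adjusted p = 0.331 with an estimated correlation). They included itpr3, a receptor channel that releases stored calcium (-0.77 ± 0.11 SE, limma adjusted p = 0.00104, chromosome 8, 21254192 to 21353035), and the pump gene atp2a1l (-0.55 ± 0.15, 0.0304). Calcium-binding buffer proteins, not shifted as a list (0.366), had 2 higher and 5 lower of 38, with 4 and 9 adjusted over the list alone, and s100s fell (-1.91 ± 0.23, 0.000405). Of 41 calcium channel genes 1 fell, the muscle channel gene cacna1sb (-0.36 ± 0.11, 0.0404), and 0 passed adjusted over the list alone, while the list as a whole was higher (0.15, 0.014, and adjusted p = 0.555 with an estimated correlation). In the calmodulin list camk2n2, which encodes an inhibitor of CaM kinase II, was the 1 of 39 that rose (0.35 ± 0.09, 0.0223), also adjusted over the list alone (median 0.05, 0.0238, and adjusted p = 0.62 with an estimated correlation). ryr1b (-0.28 ± 0.09, 0.0563), atp2a1 (-0.38 ± 0.12, 0.0519) and pvalb4 (-0.29 ± 0.10, 0.0707) did not pass. Of the calls, cacna1sb was lost without any of 7 libraries (all but PFOS10 replicate 4, up to 0.125) and under both other scalings (0.0723 and 0.134). atp2a1l was lost without Control replicates 1, 2 or 4 or PFOS10 replicates 1 or 3 (up to 0.115) and under both scalings (0.0733 and 0.0674), and camk2n2 without Control replicates 1 or 4 or PFOS10 replicates 1 or 3 (up to 0.0741).

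Muscle lists were lower in these libraries. Of 53 skeletal muscle genes 4 fell, and 6 adjusted over the list alone (median -0.18, camera adjusted p = 0.000164), and of 16 cardiac genes actc1c fell (-0.30 ± 0.08 SE, limma adjusted p = 0.0357), 1 also adjusted over the list alone (-0.31, 0.0216). For both, adjusted p = 0.555 with an estimated correlation. actc1c was lost without Control replicates 1, 2 or 4 or PFOS10 replicates 1, 2 or 3 (up to 0.0994) and under both other scalings (0.0562 and 0.106).

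Lists of photoreceptor, neuron, glutamate and cell cycle genes lay higher in PFOS10, in the libraries that stood apart. Monoamine and cholinergic genes (46 genes, camera adjusted p = 0.39), glia and myelin genes (21 genes, 0.478) and lens crystallins (42 genes, 0.611, with 35 differences below 0) were not shifted. Of 48 photoreceptor genes 6 rose over all genes, and 7 rose and 1 fell adjusted over the list alone (median 0.19, camera adjusted p = 2.99e-08, and adjusted p = 0.339 with an estimated correlation). opn1lw2 and the green cone opsin opn1mw1 (0.34 ± 0.08 SE, limma adjusted p = 0.0183) were among them. Neuron and synapse markers had 31 of 39 differences above 0 (median 0.20, 6.2e-05, and adjusted p = 0.496 with an estimated correlation), with 1 higher and 2 lower past the test under either adjustment. The higher one was maptb, of the tau protein (0.29 ± 0.09, 0.0444), whose call was lost without any of 6 libraries (up to 0.152 without Control replicate 4; it held without Control replicate 3 or PFOS10 replicate 4) and after quantile normalization (0.0501). In the glutamate list, called higher (37 genes, 0.12, 0.0147, and adjusted p = 0.642 with an estimated correlation), the 3 members past the test fell, 3 also adjusted over the list alone, among them gls2a, a glutaminase (-1.66 ± 0.24, 0.00106). Cell cycle and DNA replication genes had 39 of 41 differences above 0 (0.21, 3.84e-06, and adjusted p = 0.555 with an estimated correlation), with 0 past the test under either adjustment.

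**Figure D3:**
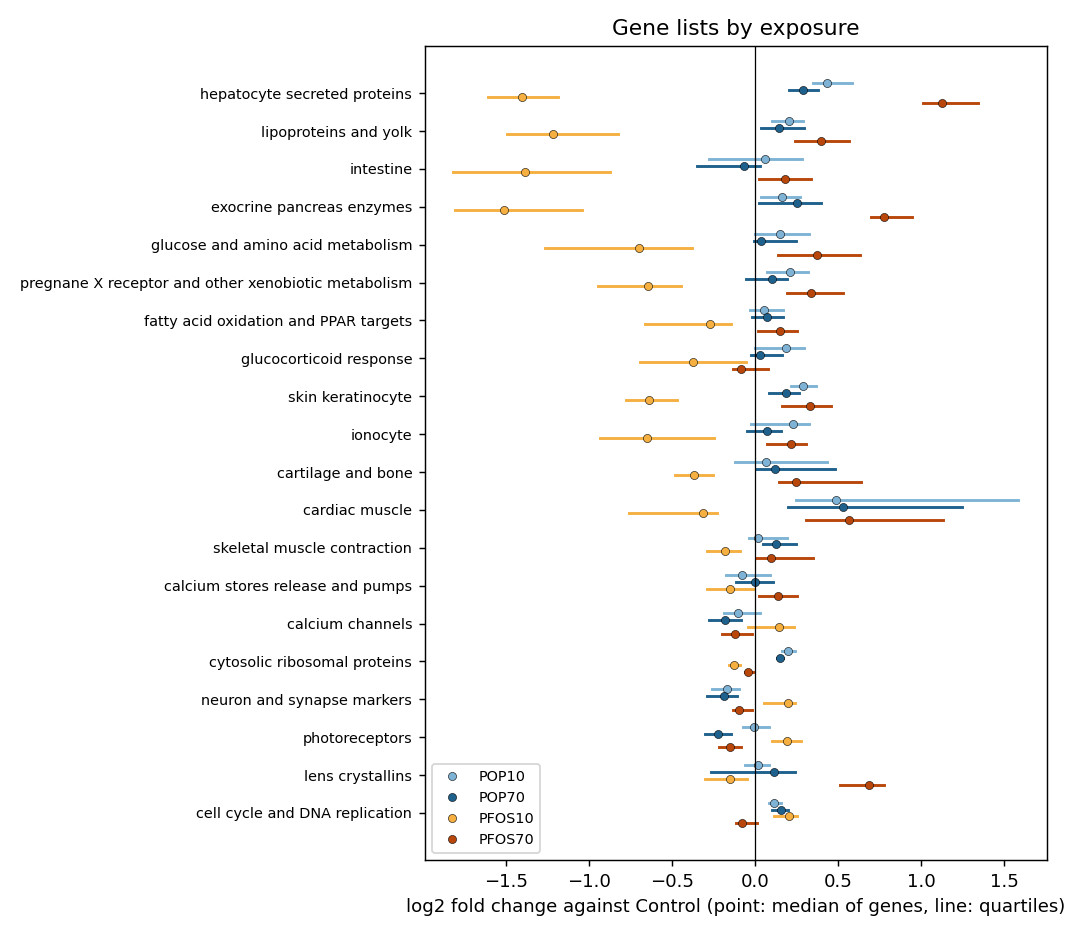
Median (point) and quartiles (line) of the log2 fold changes against Control of the genes in 20 lists, for POP10, POP70, PFOS10 and PFOS70. Hepatocyte secreted proteins have a median of -1.40 in PFOS10 and 1.13 in PFOS70; the list calls do not hold with an estimated correlation.

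The levels of PFOS were compared next. In PFOS70 larvae agxtb, an alanine-glyoxylate aminotransferase of liver, was at 7.57 ± 0.30 log2 RPM against 3.73 ± 1.47 in PFOS10 (SD, n = 4, log2 difference 3.84 ± 0.57 SE, limma adjusted p = 9.13e-05). fabp10a, the liver fatty acid binding protein gene, was at 8.23 ± 0.39 against 4.39 ± 1.78 (3.83 ± 0.61, 0.000153), and pck1 at 8.16 ± 0.30 against 4.55 ± 0.95 (3.61 ± 0.46, 3.29e-05). gadd45gb.1 (-0.86 ± 0.13, 8.9e-05), the cation channel gene trpm1a (-0.85 ± 0.14, 0.000248) and the glutamate receptor gene gria4a (-0.81 ± 0.13, 0.000176) were lower in PFOS70. The number of genes that differed was 6635, with 4558 higher in PFOS70, in a comparison with the libraries that stood apart on the first component. The sample medians differed by 0.14 log2, and 3078 of 6949 genes were higher after quantile normalization, 3475 of 8387 after a shift to equal medians and 1277 of 2651 with the stricter filter.

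The dose effect of the mixture, POP70 less POP10, was tested against that of PFOS, PFOS70 less PFOS10. They differed in 3065 of 19298 genes with limma, 511 positive and 2554 negative. After quantile normalization 1007 of 2408 were positive, after a shift to equal medians 2261 of 4249, with the stricter filter 362 of 1068 and with array weights 1453 of 5070. The number was 1871 without PFOS70 replicate 1, 1901 without PFOS70 replicate 2, 2011 without POP10 replicate 1, 1987 without POP70 replicate 3 and 1773 without POP70 replicate 4. Alone, POP70 against POP10 had 0 genes and PFOS70 against PFOS10 had 6635. The contrast holds the PFOS10 libraries that stood apart on the first component, and a batch that coincided with that group could not be separated from it.

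The stronger mixture was also compared with PFOS at the same level, which asks what the other compounds add. Relative to PFOS70, POP70 larvae had higher arrdc3b (6.81 ± 0.35 against 5.08 ± 0.20 log2 RPM, SD, n = 4) and lonrf1l (6.91 ± 0.14 against 6.11 ± 0.03). They had lower fam46ab (4.66 ± 0.15 against 5.75 ± 0.13) and serpinh1b (6.17 ± 0.36 against 7.29 ± 0.35). The log2 differences were 1.73 ± 0.24 (SE, limma adjusted p = 0.0017) for arrdc3b at chromosome 10, 43761480 to 43771447, 0.80 ± 0.07 (6.79e-06) for lonrf1l, -1.09 ± 0.13 (0.000431) for fam46ab and -1.11 ± 0.18 (0.0129) for serpinh1b. Also higher were klf11a (0.82 ± 0.14, 0.0148), arrdc3a (0.72 ± 0.13, 0.0153), mgea5, which removes sugar marks from proteins (0.72 ± 0.14, 0.0483), and the linker histone gene histh1l (0.71 ± 0.12, 0.0129). Also lower were rsrp1 (-0.70 ± 0.12, 0.0153), rbm15 (-0.56 ± 0.10, 0.0153), clk4a, a kinase of splicing factors (-0.53 ± 0.11, 0.0483), and her6 (-0.50 ± 0.09, 0.018). In total 35 genes passed, 19 higher and 16 lower, all with non-overlapping groups, and voom called 28. Of 49 genes after quantile normalization 38 were higher, and of 35 after a shift to equal medians 24.

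By list, 9 of 45 were shifted between POP70 and PFOS70, 4 higher and 5 lower. Of the 35 splits of these libraries, the real one included, 29 gave at least 9 lists. The median of the other splits was 15.5, so chance could not be excluded for this number. Of 43 circadian clock genes 3 rose, and 4 adjusted over the list alone (median 0.01, camera adjusted p = 0.000416, and adjusted p = 0.976 with an estimated correlation). These 3 were nfil3 (0.65 ± 0.08 SE, limma adjusted p = 0.000651), ciarta, a repressor of the clock (0.41 ± 0.07, 0.018), and nfil3-5 (0.60 ± 0.12, 0.043). Of 41 cell cycle genes ccne2, a cyclin (0.69 ± 0.14, 0.0494), rose, and 2 adjusted over the list alone (0.19, 4.21e-12, and adjusted p = 0.976 with an estimated correlation). Ribosomal protein genes were higher (75 genes, 0.18, 5.74e-32) and hepatocyte secreted proteins (29 genes, -0.82, 2.07e-09) and lens crystallins (42 genes, -0.55, 3.04e-10) lower, with 0 members past either adjustment and adjusted p = 0.976 with an estimated correlation. Calcium stores, release and pumps lay lower (44 genes, -0.15, 0.000991, and adjusted p = 0.679 with an estimated correlation), also with 0 members. Outside these lists, jun (-0.47 ± 0.08, 0.0129) and the heat shock gene dnajb1b (-0.84 ± 0.16, 0.0257) were lower. The number of lists was 17 without POP70 replicate 1 and 16 without POP70 replicate 2.

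Single libraries decided much of the POP70 and PFOS70 difference. The 35 genes became 16, 11, 4 and 17 without PFOS70 replicates 1, 2, 3 and 4, and 14, 14 and 9 without POP70 replicates 1, 3 and 4. Of 18 named genes, arrdc3b, lonrf1l, fam46ab and nfil3 passed with each library left out. Without PFOS70 replicate 3 the adjusted p was 0.0593 for serpinh1b, 0.0766 for jun, 0.0827 for histh1l, 0.095 for rbm15, 0.0968 for rsrp1 and arrdc3a, 0.111 for her6, 0.133 for dnajb1b and 0.231 for clk4a. Without POP70 replicate 4 it was 0.079 for klf11a, 0.196 for nfil3-5, 0.198 for mgea5 and 0.242 for ccne2, and without PFOS70 replicate 2 it was 0.0943 for ciarta. Each of these is the highest value for its gene, and most calls were lost without other libraries too. mgea5, ccne2 and nfil3-5 were lost without any of 7 libraries, and her6, dnajb1b and clk4a without any of 6. The number was 5 for arrdc3a and ciarta, 4 for klf11a and histh1l, 3 for rsrp1 and rbm15, 2 for jun and 1 for serpinh1b. clk4a was also lost under both other scalings (0.0647 and 0.0851).

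At the lower level the mixture and PFOS differed widely. Relative to PFOS10, POP10 larvae had higher pck1 (7.97 ± 0.59 against 4.55 ± 0.95 log2 RPM, SD, n = 4), rhcga (6.80 ± 0.66 against 3.51 ± 0.38), agxtb (6.88 ± 0.83 against 3.73 ± 1.47), fabp10a (7.09 ± 0.32 against 4.39 ± 1.78), fkbp5 (8.82 ± 0.21 against 6.31 ± 0.44) and cyp24a1, which inactivates vitamin D (6.34 ± 0.25 against 3.85 ± 0.48). The log2 differences ran from 2.49 ± 0.37 (SE, limma adjusted p = 0.000217) for cyp24a1 to 3.42 ± 0.46 (0.000109) for pck1. Lower were the hypothalamic otpa (-0.95 ± 0.20, 0.00198), foxb1a (-0.94 ± 0.25, 0.00791), cspg5a (-0.88 ± 0.21, 0.00518), shisa6 (-0.84 ± 0.20, 0.004), the synaptic nrxn2b (-0.84 ± 0.22, 0.00784) and serpinh1b (-0.84 ± 0.18, 0.00256). In total 6054 of 19298 genes passed, 3815 of them higher in POP10. The sample medians differed by 0.10 log2, and 2692 of 5608 genes were higher after quantile normalization, 3030 of 7206 after a shift to equal medians and 1222 of 2978 with the stricter filter.

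Between POP10 and PFOS10, 27 lists were shifted, 21 higher and 6 lower, beside the PFOS10 libraries' separate place on the first component. All 29 hepatocyte secreted proteins rose, 29 also adjusted over the list alone (median 1.87, camera adjusted p = 1.88e-12), rbp4 among them (0.93 ± 0.15 SE, limma adjusted p = 0.000379). Of 21 glucocorticoid response genes 13 rose and 2 fell, the same numbers as adjusted over the list alone (0.50, 1.2e-05), with klf9 (2.93 ± 0.27, 4.23e-06) and tsc22d3 (0.98 ± 0.11, 2.64e-05). Of 25 keratinocyte genes 22 rose, and 23 adjusted over the list alone (0.88, 5.84e-11), and of 39 neuron and synapse markers 22 fell and 2 rose, with 25 and 2 adjusted over the list alone (-0.31, 1.06e-08). For these 4 lists adjusted p = 0.312 with an estimated correlation. Calcium channels had 13 of 41 lower and 0 higher, with 13 and 1 adjusted over the list alone (-0.22, 0.00122, and adjusted p = 0.429 with an estimated correlation). Calcium stores, release and pumps had 11 of 44 higher and 3 lower (adjusted p = 0.511), and calcium-binding buffer proteins 17 of 38 and 5 (0.212), and neither list was shifted. Of their members itpr3 (0.64 ± 0.11, 0.000504), s100s (2.42 ± 0.23, 4.62e-06) and pvalb4 (0.57 ± 0.10, 0.00058) were higher in POP10.

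The 4 correlations of log2 fold changes across the 19298 genes were computed last. These genes are not independent replicates, and the comparisons share the Control libraries, so a correlation of 0.50 and a covariance of 0.0248 came with no effect in 100 simulations. Fold changes of POP70 and PFOS70 correlated at 0.515 (covariance 0.0341), and at 0.146 on average over 6 splits of the controls (0.000777 to 0.287). For POP10 and POP70 the values were 0.682 (0.0385) and 0.214 (0.126 to 0.277). PFOS10 and PFOS70 fold changes correlated at -0.454 (-0.0512), and at -0.652 to -0.347 with split controls, and POP10 and PFOS10 at -0.236 (-0.0228), and at -0.530 to -0.115. Without Control replicate 3 the last 2 correlations were -0.293 and -0.02, with no filter -0.242 and -0.041, and without Control replicate 2 that of POP10 and PFOS10 was -0.145. With the stricter filter these 2 pairs gave -0.676 and -0.498. Without POP70 replicate 1 the correlation of POP70 and PFOS70 was 0.38 and that of POP10 and POP70 was 0.495.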

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

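Of the tests in this part, those of scaling, of the placement on the first component and of the time of day were chosen after the result was seen. The difference of dose effects, with its 100 groupings, was also added after the data were seen, while the tests over the 35 splits of each comparison, of thinned reads and of a shared axis were set before.

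The PFOS10 libraries lay apart from the other 16, with 1592 genes past the threshold against Control. Tests argue against scaling by a few abundant genes as the whole cause, as 798 genes still passed after quantile normalization, and against depth, as 1546 passed after thinning to 8572287 reads (1393 in both). Along the PFOS10 less Control direction lay 9.56% of the variance within POP10, POP70 and PFOS70, against 28.8% along its leading component, a ratio of 0.332 that falls between the bounds set, so an axis on which larvae of 1 group also differ cannot be told apart from an effect. Chance could not be excluded for the 1592 genes, as 2 of the 35 splits gave as many and the highest other, with Control replicates 1, 2 and 4 and PFOS10 replicate 4 on 1 side, gave 1744. An effect of PFOS, mislabelled libraries and an unlabelled difference in clutch, handling or stage that may coincide with the group all stay open.

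PFOS10 and PFOS70 fold changes against Control ran in opposite directions, with a correlation of -0.454 (-0.293 without Control replicate 3 and -0.242 with no filter). Controls shared by both comparisons gave 0.50 in simulations with no effect, so they act against this sign. Parting on the first component, 30.4 between the means of PFOS70 and Control, was matched by 2 of 35 splits of these 8 libraries (highest other 33.1), so a chance placement of the PFOS70 and Control libraries on an axis that PFOS10 defines may account for the sign. A dose effect of PFOS that is not monotonic stays open as a hypothesis.

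POP70 and PFOS70 parted in 35 genes, and no other of the 35 splits called any (real 35, highest other 0, 1 split as large). This argues against chance. However, 1 of 35 is the smallest share such splits can give, and the split tests were not corrected for their number. Passing genes fell to 4 without PFOS70 replicate 3 and to 12 with only these groups fitted. Depth is argued against, as 35 genes passed after thinning, 33 of them in both. A difference in the time of day of sampling predicts that many clock genes move, and 4 of 43 passed adjusted over the list alone (4 to 7 with 1 library left out), under the bound of 5 set for arguing against it but not over the whole range, so it cannot be told apart from an effect of the other compounds of the mixture. That the decision rests on this range was settled after the value was seen.

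The dose effects of the mixture and of PFOS differed in 3065 genes by a test of the difference itself. Of 100 groupings 1, the real one, gave as many (highest other 1653). The groupings mixed the libraries of all 4 exposed groups, so the PFOS10 libraries standing apart for any reason would also set the real one apart. They cannot tell whether the dose effects differ, and no conclusion is drawn from them. Splits of 8 libraries argue against chance for POP10 against PFOS10 (6054 genes, 1 of 35 splits, highest other 894) and PFOS70 against PFOS10 (6635, 1 of 35, highest other 2292). They do so also for the lists of PFOS10 against Control at the preset correlation (31, 1 of 35, highest other 26). In each, 1 of 35 was the smallest share possible, with no correction for the number of tests. With an estimated correlation 0 of these PFOS10 lists passed (smallest adjusted p = 0.331), and the median of the other splits at the preset was 19 lists. In the other comparisons of lists that median ran from 15.5 for POP70 against PFOS70 to 21.5 for POP10 against PFOS10. Chance could not be excluded for POP70 against Control (3 genes, 2 of 35, highest other 3), nor for the lists of POP70 (20, 12 of 35, highest other 27), POP10 (17, 16 of 35, highest other 25) and PFOS70 (27, 3 of 35, highest other 33) against Control, of POP70 against PFOS70 (9, 29 of 35, highest other 26) and of POP10 against PFOS10 (27, 4 of 35, highest other 29). With limma calling 0 genes, 35 of 35 splits were as large for POP10 against Control, PFOS70 against Control and POP70 against POP10, where 1857, 2259 and 580 genes had an unadjusted p under 0.05 and voom called 0 in each. Their highest other splits gave 1, 40 and 133 genes, with a median of 0 over the other splits. The 40 and 133 point to a structure of the samples other than the groups, but whether such counts exceed chance in correlated genes was not tested.

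Single libraries stood far from the rest of their group in 18 of 478 groups of 4 values, where 24 would come by chance at 1 in 20. Each had a gap to the nearest library, over the range of the group, above Dixon's critical value for groups of 4. This ratio was 0.965 for the reads of Control replicate 4 (10140000 against a mean of 10930000 in the others) and 0.887 for the transcripts at 0 reads of PFOS10 replicate 3 (4120 against 4019). For list means in log2 RPM it was 0.865 for immediate early genes in Control replicate 4 (4.81 against 4.62), 0.905 for cell cycle genes in POP10 replicate 3 (6.17 against 5.81) and 0.926 for ionocyte genes in POP10 replicate 4 (4.89 against 5.17). In PFOS10 it was 0.872 for the glucocorticoid response in replicate 3 (5.54 against 5.24) and 0.874 for the circadian clock in replicate 4 (5.49 against 5.73). Of single genes, Control replicate 4 had 0.863 for gnmt (5.399 against 4.664) and 0.83 for gad1b (9.15 against 9.03), and PFOS10 replicate 4 had 0.972 for pvalb4 (9.39 against 8.90) and 0.931 for cspg5a (8.74 against 9.17). POP10 libraries had 0.889 for itpr3 (replicate 3, 5.74 against 6.07), 0.861 for atp2a1 (replicate 2, 12.89 against 12.75) and 0.907 for zmynd8 (replicate 4, 5.63 against 5.17). POP70 libraries had 0.898 for cyp1b1 (replicate 4, 2.33 against 2.73), 0.847 for rbm15 (replicate 4, 5.33 against 5.56) and 0.851 for her6 (replicate 3, 4.66 against 4.80), and PFOS70 replicate 2 had 0.881 for mgea5 (7.35 against 7.29).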

How the results depend on the processing

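The fit without the PFOS10 libraries, the choices of transcript and all alternatives for the difference of dose effects were added after seeing the data. POP70 against POP10 had 0 genes under each alternative that was run. No named gene past the threshold changed direction, and no called list had a median of the other sign under both other scalings. The remaining genes were not checked for this. The share of higher genes in the large counts depended on scaling, the filter, array weights and single libraries. After a shift to equal medians most genes were lower in POP10 against PFOS10 (3030 of 7206 higher) and PFOS70 against PFOS10 (3475 of 8387). Causes of the changes given here were not tested, except that the stricter filter tests fewer genes and a fit of 2 groups or without a library has fewer samples.

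The stricter filter gave 8 genes for POP70, 3 for PFOS70 and 610 (187 higher) for PFOS10 against Control, 2978 for POP10 against PFOS10 (1222 higher), 2651 for PFOS70 against PFOS10 (1277 higher) and 1068 (362 positive) for the difference of dose effects. Its correlations were -0.498 for POP10 and PFOS10, 0.819 for POP10 and POP70 and -0.676 for PFOS10 and PFOS70. No filter gave 1 gene for POP10 and 13 lists for POP70, and correlations of -0.041 for POP10 and PFOS10 and -0.242 for PFOS10 and PFOS70. Damped values gave 769 genes for PFOS10 and correlations of -0.421, 0.784 and -0.603 for POP10 and PFOS10, POP10 and POP70, and PFOS10 and PFOS70. Quantile normalization gave 6 genes for POP70, 7 for PFOS70 and 798 for PFOS10, 15 lists for POP70 against PFOS70, and correlations of -0.153 and -0.386 for POP10 and PFOS10 and for PFOS10 and PFOS70. A shift to equal medians gave 4 genes for PFOS70. Array weights gave 7 genes for PFOS70, 3664 (1101 higher) for PFOS10 and 5070 (1453 positive) for the difference of dose effects. Fits of only the groups compared gave 0, 4, 6 and 934 genes for POP70, POP10, PFOS70 and PFOS10 against Control and 12 for POP70 against PFOS70. The fit without the PFOS10 libraries gave 8 genes for POP70. With an estimated correlation, 0 lists passed in POP70, POP10, PFOS70 and PFOS10 against Control, 0 in POP70 against PFOS70 and 0 in POP10 against PFOS10.

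With 1 library left out, genes past the threshold ranged from 2 to 9 for POP70, 0 to 3 for POP10, 0 to 16 for PFOS70 and 368 to 2518 for PFOS10 against Control. They ranged from 4 to 45 for POP70 against PFOS70, 4252 to 6888 for POP10 against PFOS10, 4989 to 7345 for PFOS70 against PFOS10, 0 to 0 for POP70 against POP10 and 1773 to 4146 for the difference of dose effects. Lists ranged from 15 to 27 for POP70, 10 to 22 for POP10, 23 to 28 for PFOS70 and 25 to 32 for PFOS10 against Control, 10 to 17 for POP70 against PFOS70 and 27 to 29 for POP10 against PFOS10. Correlations ranged from 0.38 to 0.617 (POP70 and PFOS70), -0.264 to -0.02 (POP10 and PFOS10), 0.495 to 0.74 (POP10 and POP70) and -0.494 to -0.293 (PFOS10 and PFOS70). Without Control replicate 3 the values were -0.02 for POP10 and PFOS10 and -0.293 for PFOS10 and PFOS70, and without Control replicate 2 the former was -0.145. Without Control replicate 4 the genes were 9 for POP70, 3 for POP10, 16 for PFOS70 and 368 for PFOS10. PFOS10 genes also moved over 1.5 times without Control replicates 1 (737) and 2 (657) and PFOS10 replicates 1 (723), 3 (739) and 4 (2518), and PFOS70 genes without PFOS70 replicate 3 (5). For POP70 against PFOS70 such libraries were PFOS70 replicates 1 to 4 (16, 11, 4 and 17) and POP70 replicates 1, 3 and 4 (14, 14 and 9). For lists they were Control replicate 3 in POP10 (10) and POP70 replicates 1 and 2 in POP70 against PFOS70 (17 and 16). For the difference of dose effects they were PFOS70 replicates 1 and 2 (1871 and 1901), POP10 replicate 1 (2011) and POP70 replicates 3 and 4 (1987 and 1773).

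The labels do not say what a replicate number shares, and same-numbered libraries were only weakly alike across genes. Over 10 pairs of groups they correlated at -0.0957 to 0.194, with 2 over 0.1, and 3 of 20 libraries correlated best with their own number. Pairs of exposed groups were all positive (0.0658 to 0.194) and pairs with Control ran from -0.0957 to 0.0278, so pairing is not ruled out. With the number as a block, 6 genes passed for POP70, 15 for PFOS70, 0 for POP10 and 1959 for PFOS10 against Control. Of 340 pairs of a named gene and a comparison, 267 passed the threshold. Their calls were lost in 52 with only the groups compared, 40 after quantile normalization, 38 with damped values, 25 without the variance trend, 23 after the median shift, 22 with no filter and 13 with voom, and in 329 cases with 1 library left out. A gene at 0 log2 RPM rests on 8.57 reads in the shallowest library, so counting error limits the folds of such genes.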

Other observations

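Some gene groups moved between POP10 and PFOS10 beyond those of the comparison above, in the libraries that stood apart on the first component. Of 75 cytosolic ribosomal protein genes 66 rose in POP10, and 71 adjusted over the list alone (median log2 difference 0.32, camera adjusted p = 1.34e-16, and adjusted p = 0.398 with an estimated correlation). Of 18 erythrocyte genes 11 rose, and 13 adjusted over the list alone (0.65, 0.000532, and adjusted p = 0.424 with an estimated correlation). Of 16 cardiac muscle genes 11 rose and 1 fell, and 12 and 1 adjusted over the list alone (0.75, 3.63e-05, and adjusted p = 0.312 with an estimated correlation), with myh7l at 2.23 ± 0.36 (SE, limma adjusted p = 0.000401). Of 64 nuclear genes of oxidative phosphorylation 21 rose, and 26 adjusted over the list alone (0.18, 1.59e-06, and adjusted p = 0.494 with an estimated correlation). Other genes higher in POP10 were the ionocyte genes slc12a10.2 (1.47 ± 0.19, 6.06e-05) and rhcgb (1.72 ± 0.26, 0.000238), col10a1a (2.1 ± 0.28, 8.31e-05), gch2 (1.05 ± 0.17, 0.000449), krt15 (1.24 ± 0.18, 0.000199) and nfkbiaa (1.29 ± 0.18, 0.000118). These 7 single genes are named in other comparisons above, and their values here were chosen after being seen. In each the 4 POP10 values lay above the 4 PFOS10 values, and each passed with any 1 library left out and under both other scalings.

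Bile acid, antioxidant and immediate early genes were lower in PFOS10 than in Control, in the same libraries. Of 11 bile acid handling genes 6 fell, and 8 adjusted over the list alone (median -1.04, camera adjusted p = 0.000194, and adjusted p = 0.331 with an estimated correlation). Of 34 oxidative stress genes 7 fell, and 14 adjusted over the list alone (-0.27, 9e-06, and adjusted p = 0.339 with an estimated correlation). Of 25 immediate early genes 7 fell, and 8 adjusted over the list alone (-0.20, 0.0164, and adjusted p = 0.555 with an estimated correlation). Lens crystallins were not shifted in PFOS10 (42 genes, -0.15, 0.611), and sterol synthesis genes were not either (26 genes, -0.04, 0.946, with the median at 0.02 after quantile normalization and 0.05 after a shift to equal medians).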
